A study of Caenorhabditis elegans with 2 samples.

How the data were processed

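Chromatin immunoprecipitation with sequencing (ChIP-seq) of RPC-1, the largest subunit of RNA polymerase III (Pol III), was analysed from 2 libraries of whole Caenorhabditis elegans young adults. Per the labels, the worms were a mixed-sex population of strain YL517, a transgenic line in which RPC-1 carries a GFP-FLAG tag at its C terminus, and chromatin was sheared by sonication. Both libraries belong to 1 group and are labelled as biological replicates 1 and 2. The labels give them separate biosample records and do not say how the cultures were grown. One free-text label names the target as PRC-1, while the antibody, strain and line descriptions name rpc-1, which was used here. No second group of libraries was analysed, so every test was over genes, peaks or regions of these libraries and none compared conditions.

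The deposited files used here are peak lists in narrowPeak format on the ce11 build, with the same lists on ce10 as an alternative. Per the deposited file descriptions, each replicate list was made from that replicate's alignments together with a control alignment, and the pooled list from the alignments of both replicates. The optimal list came from those 3 lists through the irreproducible discovery rate (IDR), which rates how alike peaks rank in the replicates. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is a score from the authors' peak caller, with no fixed range, and signal values were compared only within 1 list, apart from the rank correlation between the replicates. The deposited −log10 q column has 1 shared highest value per list. All 2123 optimal peaks held that value (3.78), so it was not used for ranking. Every optimal peak was also among the 2123 peaks of highest signal value of the pooled list, with the same interval, summit and signal value, so the top of the pooled list could not differ from the optimal list in any result. Read counts and depth per library were not used here and are unknown for these values. The Wilson 95% intervals cover counting error over genes or peaks only. Control libraries were not analysed here.

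The optimal list held 1857 distinct intervals for its 2123 peaks, since some intervals carry more than 1 summit, each as a peak of its own. Each peak was counted, and merging overlapping peaks was an alternative. Genes came from the RefSeq annotation of WBcel235, the assembly that ce11 names, and no peak ran past a chromosome end in it. Coordinates are 1-based on ce11. Pol III genes were the nuclear tRNA genes, the 5S rRNA and U6 snRNA genes, and the RNase P, RNase MRP, SRP and Y RNA genes, 660 in all. Stem-bulge RNA genes, also fixed as Pol III genes, are not named as such in this annotation and were not analysed as a class. The snRNA genes were typed by short conserved sequences of each snRNA, which left 27 untyped. Mitochondrial tRNA genes (22) were left out. The Pol II small RNA genes used as a control were the U1, U2, U4 and U5 snRNA genes and the SL1 and SL2 spliced leader RNA genes, 78 in all.

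A gene counted as occupied where its body, widened by 100 bp on each side, overlapped an optimal peak by at least 1 bp. Each peak received 1 class in a fixed order: tRNA gene, other Pol III gene, tRNA pseudogene, Pol II snRNA or SL RNA, snoRNA, other non-coding gene, protein-coding promoter (within 500 bp of an annotated transcript start), protein-coding gene body, no gene. Shares were compared with 1000 random placements of the same peaks within their chromosomes (bedtools shuffle), with a one-sided permutation test whose smallest p is 0.000999. Shares of gene groups were compared by two-sided Fisher exact tests. Isotype tests and the 10 preset promoter lists were adjusted by the Benjamini-Hochberg method, each family over its own tests. Isotypes with at least 5 genes were tested, and 5 tRNA genes with no annotated isotype were left out of that test. The design asked for this, and it was put into effect after a first analysis of the data, so the test was also done with these 5 genes as a class. Medians of signal values were compared by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05. The B box, the part of the tRNA promoter bound by TFIIIC, was searched as GTTCRANNC on either strand within 100 bp of the summit. The significance threshold was 0.05.

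Named genes followed a rule fixed before the data were examined: the 10 highest optimal peaks with the highest-ranked class gene each overlapped, the 10 non-tRNA Pol III genes of highest signal value, the 10 highest promoter peaks over 1 kb from any Pol III gene, up to 4 members of each preset list with a peak, the highest tRNA gene of each chromosome, rpc-1 and unc-119, and the isotypes with the highest and lowest share. Genes named outside the rule are said to be so, except host and neighbouring genes given only to place a peak. The preset lists count any peak that reaches a promoter, whatever the class of that peak. The groups, tests, preset lists and most alternatives were also fixed before the data were examined. Alternatives were a stricter threshold (the 1061 optimal peaks of higher signal value), 3 other definitions of an occupied gene, the top 2123 peaks of 1 replicate list alone, the pooled list, the ce10 files, merged tRNA units, other promoter widths, other B-box windows and another B-box motif. Merged peaks, control genes over 1 kb from any Pol III gene, genes with no annotated isotype as a class (alone, with the stricter threshold and with 50% of the gene body covered), and preset lists without promoters within 1 kb of a Pol III gene were added after the data were seen.

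Tested on simulated data were 11 tests: the shares of tRNA genes, of peaks at Pol III genes, of promoters and of B boxes against placements, the 4 Fisher tests of gene groups, the isotypes, the preset lists and the medians of signal values. The placement tests of other gene classes and the tests of the closing section were not. Over 100 simulated lists of 2000 random peaks, each of the 11 passed the threshold in 1 to 8 lists. The simulated peaks had equal width and independent positions, and fewer placements and resamples were used. The shared intervals and overlapping peaks of the real list were not simulated, so these rates need not hold for it. With peaks planted at 367 tRNA genes, 100% of these were found, and 17.1% of the other 245 tRNA genes were also called occupied; a peak can be shared by neighbouring tRNA genes. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.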

Results

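RPC-1 occupancy was measured by ChIP-seq in whole young adult worms that carried a GFP-FLAG-tagged RPC-1, in 2 biological replicates of 1 group. RPC-1 is the largest subunit of RNA polymerase III, the enzyme that transcribes tRNA, 5S rRNA, U6 snRNA and several other short non-coding RNAs. The optimal IDR list on ce11 held 2123 peaks, which merged into 1669 regions covering 1151583 bp, or 1.15% of the genome. Peak width had a median of 623 bp with quartiles of 455 and 848.5 bp. The signal value, the authors' score for each peak, ran from 60.0 to 9672 with a median of 355. The X chromosome carried 569 of the peaks (26.8%), or 32.1 peaks per Mb, against 16.7 to 21.8 per Mb on the autosomes. X also carried 276 of the 612 annotated nuclear tRNA genes (45.1%).

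The replicates were compared first. The full list of replicate 1 held 26455 peaks and overlapped 2119 of the optimal peaks (99.8%), and that of replicate 2 held 27629 and overlapped 2118 (99.8%). The 2123 strongest peaks of replicate 1 overlapped 2029 of the optimal peaks, those of replicate 2 overlapped 2018, and 91.6% of the optimal peaks were overlapped by both. Across 2114 peaks found in both lists, the signal values of the replicates ranked alike, with a Spearman rho of 0.982. This value is across peaks, which are not independent replicates. The optimal peaks were also the highest of a pooled list made from both replicates, so they were not chosen independently of either.

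Nuclear tRNA genes were occupied almost throughout. Of 612 tRNA genes, 595 (97.2%, Wilson 95% interval 95.6 to 98.3) had an optimal peak, against a mean of 2.48% and a highest value of 5.56% over the random placements (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). The occupied tRNA genes had a median signal value of 3306 with quartiles of 2185 and 4145. Of the 17 tRNA genes without an optimal peak, 8 had a weaker peak in the pooled list and 4 had none in any list. Those 4, named after their values were seen, were Y75D11A.t2 (Arg), K02D3.t1, F28H6.t3 (His) and F28H6.t6 (His), all on X. Of the 36-base words in these genes, each widened by 100 bp on each side, 69.0%, 96.5%, 0% and 11.8% were unique in the genome. The sequence of both His genes with these flanks is therefore largely repeated elsewhere.

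By the fixed rule, the highest tRNA gene of chromosome I was F15D3.t1, a Lys tRNA gene at 11579706 to 11579778, with a signal value of 4440. On II it was ZK622.t1 (Ala, 5106), on III F52C9.t1 (Thr, 5261) and on IV B0350.t1 (Lys, 5663). On X it was M02F4.t2 (Glu, 8035), whose peak had its summit nearer to the adjacent Gly tRNA gene M02F4.t1 (named after its values were seen), at 23 bp from it against 94 bp from M02F4.t2. On V the rule gave ZK994.t2 (Lys), because it overlapped an interval with a signal value of 9368. The summit of that peak lay 934 bp from ZK994.t2 and 9 bp from the snoRNA gene ZK994.7 (also named after its values were seen), and the summit within 100 bp of ZK994.t2 itself had a signal value of 3070. A peak can span neighbouring genes, and the share of tRNA genes with a summit within 100 bp was 91.2%.

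Intact tRNA genes and tRNA pseudogenes differed. Of 209 annotated tRNA pseudogenes, 56.9% had a peak (interval 50.2 to 63.5) and 90 had none; the share was 40.3 percentage points below the tRNA genes (two-sided Fisher exact p = 8.31e-44). Occupied pseudogenes had a median signal value of 253, against 3306 at tRNA genes. Pseudogenes were still occupied above the random placements, whose mean was 1.99% and highest value 6.22% (permutation p = 0.000999, the smallest possible). Among the 1061 optimal peaks of higher signal value, 46 pseudogenes (22.0%) and 576 tRNA genes (94.1%) were occupied, and the difference was 72.1 points (Fisher exact p = 9.68e-92).

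Occupancy was nearly complete in every part of the tRNA gene set that was compared. On X, 270 of 276 tRNA genes (97.8%) had a peak, and on the autosomes 325 of 336 (96.7%), a difference of 1.1 points that did not pass the test (two-sided Fisher exact p = 0.467). With the stricter threshold, the share on X was 96.4% and that on the autosomes 92.3%, a difference of 4.11 points that did pass (Fisher exact p = 0.0377). That threshold is a cut on signal value, whose median over occupied tRNA genes was 4010 on X and 2726 on the autosomes. Neighbouring tRNA genes can share a peak, and they were not merged at this threshold. When a summit within 100 bp was required, the shares were 89.1% on X and 92.9% on the autosomes, the opposite order (difference of −3.73 points, Fisher exact p = 0.116). Of the 291 tRNA genes that lay inside protein-coding genes, 282 (96.9%) were occupied, and of the other 321, 313 (97.5%); the difference of −0.60 points did not pass the test (Fisher exact p = 0.806), and its sign turned with the definition of an occupied gene.

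All 20 isotypes were represented. For 10 of them every gene had a peak: Asn, Asp, Cys, Gln, Glu, Ile, Pro, Ser, Thr and Trp. The lowest shares were those of His and Met, each with 18 of 20 genes (90.0%, interval 69.9 to 97.2). The His genes without a peak were F28H6.t3 and F28H6.t6, the pair of largely repeated sequence, which also count as unoccupied in the alternatives below. None of the 20 isotypes differed from the others past the threshold by Fisher's exact test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.939, lowest unadjusted p = 0.0939). When at least 50% of the gene body had to be covered, 16 of 20 His genes (80.0%) were occupied, and His alone passed (adjusted Fisher exact p = 0.0486). That call depended on leaving out the 5 genes with no annotated isotype, which was settled after a first analysis of the data. With these 5 as a class of their own, His did not pass (adjusted Fisher exact p = 0.0605). With that class and the stricter threshold, both His (15 of 20, adjusted Fisher exact p = 0.0454) and the class itself (2 of 5, adjusted p = 0.0363) passed.

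**Figure D1:**
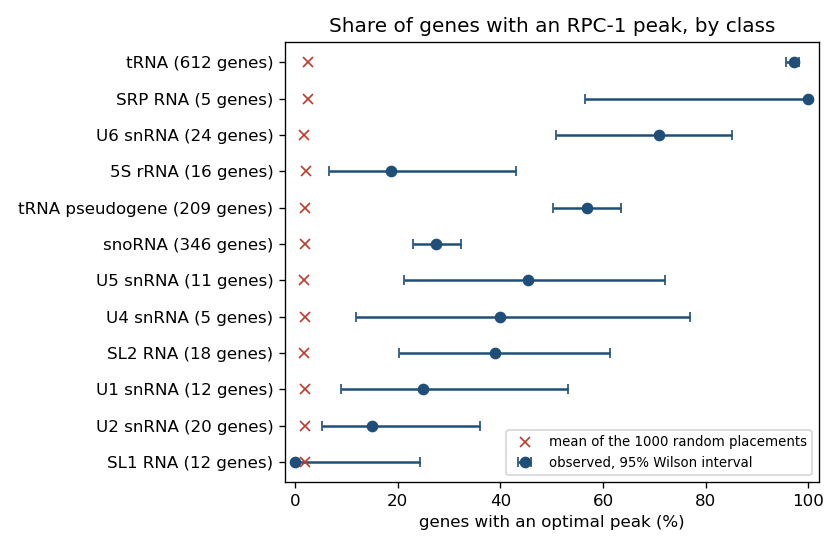
Share of genes with an optimal RPC-1 peak, in percent on the x axis, by gene class on the y axis; points are observed shares with 95% Wilson intervals and crosses are the mean of 1000 random placements. tRNA genes stood at 97.2%, tRNA pseudogenes at 56.9% and SL1 RNA genes at 0%.

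Pol III genes as a whole were occupied more often than small RNA genes transcribed by Pol II. Of 660 Pol III genes, 623 (94.4%, interval 92.4 to 95.9) had a peak, against 20 of 78 U1, U2, U4, U5, SL1 and SL2 genes (25.6%, interval 17.3 to 36.3), a difference of 68.8 points (two-sided Fisher exact p = 2.19e-43). The share at the Pol II genes was still above the random placements, with a mean of 1.84% and a highest value of 8.97% (permutation p = 0.000999, the smallest possible). The peaks at the Pol II genes were weak, with a median signal value of 76.0 over the occupied genes, against 3267 over the occupied Pol III genes. The exceptions above 1000 were the SL2 gene sls-2.9 (3965) and the U5 gene C53D6.12 (1383), and neither had a summit within 100 bp. By the class order, both peaks belonged to a Pol III gene or a tRNA pseudogene. The highest peak of the Pol II snRNA or SL RNA class had a signal value of 163. With the stricter threshold, 2 of the 78 (2.56%) stayed occupied and 90.8% of the Pol III genes did.

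Outside the tRNA genes, the single-copy Pol III genes were all occupied. These were rpr-1, the RNA of RNase P, which trims tRNA 5′ ends (chromosome I, 13463955 to 13464207), with a signal value of 3487, mrpr-1, the RNA of RNase MRP (II, 7200233 to 7200418), with 3121, and the Y RNA gene yrn-1 (IV, 7499508 to 7499612), with 2971. All 5 genes of the signal recognition particle RNA had a peak, from srpr-3 at 96.6 to srpr-2.1 at 1145, both named after their values were seen. The U6 snRNA genes, which encode the catalytic snRNA of the spliceosome, were occupied in 17 of 24 cases (70.8%, interval 50.8 to 85.1). W05B2.8 (III, 10989679 to 10989780) had the highest signal value of all non-tRNA Pol III genes at 6175, followed among the U6 genes by F54D8.7 (3819), a U6 gene on IV at 4930954 to 4931055 (3248), T08B6.62 (3006), Y17G9A.85 (2873) and C28A5.7 (2318). Of 16 annotated 5S rRNA genes, 3 had a peak (18.8%, interval 6.59 to 43.0): rrn-4.15 (V, 17428879 to 17428996) at 2771, rrn-4.2 at 273 and rrn-4.4 at 237, the last pair named after their values were seen. The 4 annotated nuclear rRNA genes transcribed by Pol I had none (interval 0 to 49.0).

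The Pol II small RNA classes ranged from 0 of 12 SL1 genes (interval 0 to 24.2) to 5 of 11 U5 genes. Repeated sequence was not measured at these genes, so a lack of peaks cannot be read as a lack of RPC-1. The U5 genes with a peak, named after their values were seen as are the others of these classes, were C53D6.12, F38E11.10 (123), F42C5.12 (76.7), F38E11.11 (75.3) and Y69A2AR.36 (66.7). Of 18 SL2 genes, 7 had a peak, with a median signal value of 82.0. The occupied U1 genes were sup-6 (108), sup-39 (66.7) and H27M09.6 (61.2), 3 of 12. The occupied U2 genes were Y57G11C.35 (72.7), F08G2.10 (66.6) and F11A5.14 (64.7), 3 of 20. The U4 genes with a peak were C52E4.8 (80.4) and F10D2.13 (68.9), 2 of 5.

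Seen from the peaks, Pol III genes accounted for 626 of the 2123 (29.5%, interval 27.6 to 31.5), of which 586 were at tRNA genes and 40 at other Pol III genes. Random placements put a mean of 0.661% there (one-sided permutation p = 0.000999, the smallest possible). A further 135 peaks (6.36%) were at tRNA pseudogenes, 22 (1.04%) at Pol II snRNA or SL RNA genes, 95 (4.47%) at snoRNA genes and 194 (9.14%) at other non-coding genes. Protein-coding promoters held 284 (13.4%), protein-coding gene bodies 408 (19.2%), and 359 (16.9%) overlapped no annotated gene. The share at Pol III genes was higher among stronger peaks: it was 79.6% among the 530 strongest peaks, then 25.8%, 8.47% and, among the 531 weakest, 4.14%. The stricter threshold accordingly gave 52.7%.

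The strongest peaks were at tRNA genes and at snoRNA genes, whose RNAs guide the chemical modification of rRNA. The median signal value was 2892 for tRNA gene peaks (quartiles 1701 and 4000), 1869 for snoRNA peaks (129 and 4922), 647 for other Pol III genes, 218 for tRNA pseudogenes, 167 for protein-coding promoters and 71.1 for Pol II snRNA or SL RNA genes. The median of tRNA gene peaks exceeded that of promoter peaks by 2726 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). In the list of replicate 1 alone the 2 medians were 1664 and 107, and in that of replicate 2 they were 1060 and 68.3, over the 2123 strongest peaks of each list, with the same smallest permutation p.

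The highest peak of the list was at the snoRNA gene C51F7.4 on V (12303124 to 12304166), with a signal value of 9672, and it also overlapped the protein-coding gene frm-7. The next, at 9368, was the peak 9 bp from the snoRNA gene ZK994.7 that the fixed rule assigned to ZK994.t2. The others of the 10 highest were M02F4.t2 (8035), the snoRNA genes T19B4.8 (7938), T04A8.17 (7863), F32E10.10 (7827), C04G6.12 (7797) and ZK484.9 (7528), and the tRNA genes R04D3.t2 (Val, 7493) and E03E2.t3 (Lys, 7467). Of the 346 snoRNA genes, 95 (27.5%, interval 23 to 32.4) were occupied, against a placement mean of 1.99% (permutation p = 0.000999, the smallest possible). Unclassified non-coding RNA genes (7.40% against a placement mean of 2.47%, permutation p = 0.000999) and miRNA genes (6.13% against 2.23%, permutation p = 0.004) also lay above. These gene shares counted any overlapping peak, whatever its class. The highest value at an unclassified gene, 9368, was that of the peak assigned to ZK994.t2. By the class order, other non-coding genes held 9.14% of the peaks, against a placement mean of 14.8%. Below their placement means were piRNA genes, with 114 of 15363 occupied (0.742% against 1.52%), and annotated pseudogenes other than those of tRNAs, with 51 of 1922 (2.65% against 4.97%). So were lncRNA genes (4.12% against 4.53%) and antisense RNA genes (3% against 3.68%). Peaks that share an interval were placed apart, so the lower shares cannot be read as depletion.

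**Figure D2:**
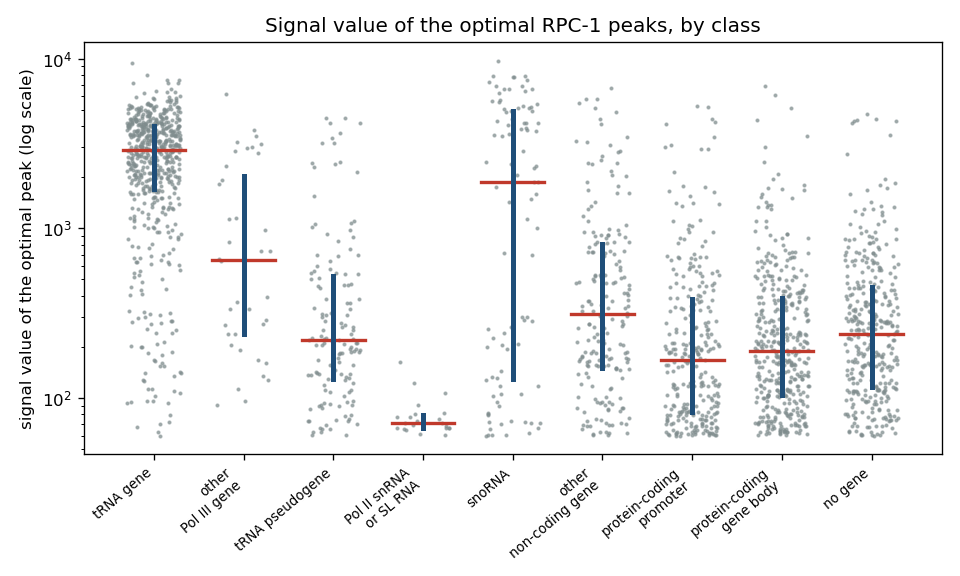
Signal value of each optimal peak, on a log scale on the y axis, by peak class on the x axis; each point is 1 peak, red lines are medians and blue bars join the quartiles. tRNA gene peaks had a median of 2892, snoRNA peaks 1869 and protein-coding promoter peaks 167.

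At tRNA genes the summit lay just inside the gene. For the 363 occupied tRNA genes with no other tRNA gene within 1 kb, the nearest summit was a median of 13 bp downstream of the gene start, in the direction of transcription, with quartiles of 11 and 16 bp. In 330 of these genes (90.9%) the summit fell within the gene, whose median length was 73 bp. The tRNA promoter consists of an A box and a B box within the transcribed region.

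**Figure D3:**
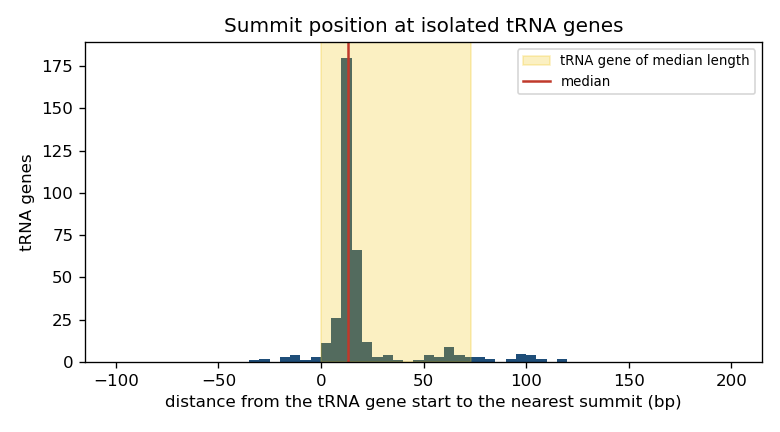
Distance in bp from the tRNA gene start to the nearest optimal summit (x axis, 5 bp bins, positive in the direction of transcription) against the number of isolated tRNA genes (y axis); shading marks a gene of the median length of 73 bp, the red line the median of 13 bp, and 2 genes lie outside the plotted range of −100 to 200 bp.

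Protein-coding promoters were occupied rarely. Of 19971 genes, 547 (2.74%, interval 2.52 to 2.97) had a peak within 500 bp of a transcript start, below the placement mean of 3.89% and the lowest placement of 3.51% (one-sided permutation p for a higher share = 1.00). Each peak was placed on its own, although some intervals carry several summits, so placements can reach more promoters than the real list. The lower share therefore cannot be read as a depletion, and merged peaks were not tested here. Without the promoters within 1 kb of a Pol III gene, the share was 1.82% (361 of 19795). The highest promoter peaks over 1 kb from any Pol III gene were nearest to the starts of F02E8.4 on X (4452871 to 4453765), with a signal value of 5289, and W08A12.2 on V (3685697 to 3686597), with 5200. They were followed by vps-37, which encodes a subunit of the ESCRT-I sorting complex (4400), by sms-3, a sphingomyelin synthase gene on III with 3 of the 10 peaks (4216, 4123 and 2926), and by D2096.7 (3439), F59A1.18 (3112), Y59E1A.4 (2917) and F39F10.2 (2153). In 6 of the 10, all but those of W08A12.2 and sms-3, the summit lay outside the 500 bp window, 541 to 936 bp from the nearest start, and only the edge of the peak reached the promoter.

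Of the 10 preset promoter lists, the ribosomal protein genes alone passed the test. A peak was present at 13 of 78 ribosomal protein promoters (16.7%), against 2.68% of the other protein-coding genes (Fisher exact p adjusted by the Benjamini-Hochberg method = 1.83e-06). These peaks were among the weakest of the list, with signal values from 60.0 to 117, led by rpl-35 (117), rpl-3 (117), rpl-18A (92.7) and rpl-15 (81.4). By the class order, 11 of the 13 genes had a peak of the promoter class, and the peaks at the other 2 belonged to a non-coding gene. The call was lost with the stricter threshold (0 of 78) and in the strongest peaks of replicate 1 alone, that is without replicate 2 (6 of 78, adjusted Fisher exact p = 0.135), and it held in those of replicate 2 alone (14 of 78, adjusted p = 1.76e-07).

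The other 9 lists did not pass. Histone genes had a peak at 2 of 72 promoters, his-70 (899) and his-42 (66.6), though by the class order the first of these peaks belonged to another non-coding gene and the second to a Pol II snRNA or SL RNA gene, and aminoacyl-tRNA synthetase genes, whose enzymes charge tRNAs, at 2 of 33, pars-2 (423) and ears-2 (64.8). Translation factor genes had 2 of 21, eif-3.C (74.3) and ife-3 (62.5), with an adjusted p of 0.559, the lowest of the 9. The germline list had 1 of 22, mex-5 (83.0), and the body wall muscle list 1 of 17, dys-1 (195). No promoter was occupied among the 15 genes of the Pol III machinery, the 16 intestinal, 17 neuronal or 15 hypodermal genes (adjusted Fisher exact p = 1 for each list).

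Peaks away from Pol III genes often contained a B box. Of the 1497 peaks of no Pol III class, 841 (56.2%, interval 53.7 to 58.7) had GTTCRANNC within 100 bp of the summit, against a placement mean of 4.34% and a highest value of 5.74% (one-sided permutation p = 0.000999, the smallest possible). The share was 72.6% at tRNA pseudogenes, 60.0% in protein-coding gene bodies, 58.8% at no gene, 54.2% at promoters, 47.9% at other non-coding genes, 40% at snoRNA genes and 9.09% at Pol II snRNA or SL RNA genes. For comparison, it was 88.6% at tRNA genes and 2.5% (1 of 40) at the other Pol III genes, of which the U6, RNase P and RNase MRP genes use promoters upstream of the gene. The share depended on the search, at 32.2% within 50 bp of the summit against a placement mean of 2.12%, and at 3.81% with the longer motif GGTTCGAANCC against 0.0363%.

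No strong peak was found at the loci linked to the transgene. No optimal peak lay within 20 kb of rpc-1 (IV, 7160135 to 7165748), the gene that was tagged, or of unc-119 (III, 10902641 to 10908935), a common marker of worm transgenes. The body of rpc-1 had no peak in any of the 4 lists. In the pooled list the highest signal value within 20 kb was 13.9 at rpc-1 and 16.3 at unc-119, against a median of 11.6 over that list. In the list of replicate 2 the highest near unc-119 was also 16.3, rank 3099 of 27629, against a median of 6.53. The body of unc-119 had 2 peaks in the pooled list, 1 in that of replicate 1 and 3 in that of replicate 2, with signal values of at most 14.9, 6.54 and 7.33.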

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

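The merged peaks, the controls over 1 kb from Pol III genes, the lists without promoters near Pol III genes and the class of tRNA genes with no annotated isotype were chosen after seeing the data. The pooled list could not differ and is left out of these counts. Of 74 alternative values of tested results, 65 kept their side of the threshold (or their count past it) and, for differences between groups, their direction. Among the 65 were all for tRNA gene occupancy (91.2 to 97.2%), Pol III genes against Pol II small RNA genes, pseudogenes, promoters, signal value and B boxes. For promoters the test asked only for a higher share than the placements, so any lower share counted as kept. Of 10 values with no test, 6 stayed within limits set by kind: 1.5 times for the peak count (1669 once merged), the 95% interval for shared peaks and rho, and 50% of the interquartile range for summits. The stricter threshold made the X minus autosome difference 4.11 points and past the threshold, left 0 preset lists past it, and raised the peaks shared by both replicates to 100% and rho to 0.984. Requiring a summit within 100 bp turned the X difference to −3.73 points and the inside minus outside difference to 3.06 points. The latter was 0.0225 points with the gene body alone and 0.334 points with 50% of it covered. None of these turned differences passed the test (lowest Fisher exact p = 0.116). With 50% of the body covered, 1 isotype (His) passed, and 0 once genes with no annotated isotype formed a class. With that class the stricter threshold gave 2, His and the class, and the main setting 0. Leaving out a replicate left 0 to 1 preset lists past the threshold. An overlap of 50% of the optimal peak gave 83.1% shared peaks and a rho of 0.976. For the other changes the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, so no limit from it can be given.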

Other observations

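All tests here were chosen after the data had been seen, except those with a prediction written before the result they measure: the explanations of the X difference, spill-over, an A box followed by a B box in all strong peaks, repeated sequence in tRNA genes and in 5S rRNA and U6 genes together, and the B box in tRNA genes with and without a peak.

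Strong RPC-1 peaks were found at many snoRNA genes, just upstream of the annotated snoRNA. Of the 346 snoRNA genes, 53 had a summit within 100 bp with a signal value of at least 1701, the lower quartile of tRNA gene peaks. In 45 of these 53 the summit lay upstream of the snoRNA start. Over all 53 the median position was −44 bp, with quartiles of −54 and −16 bp. Of the 53, 31 (58.5%) lay inside a protein-coding gene, against 62.1% of the other 293 snoRNA genes, a difference that did not pass Fisher's exact test (p = 0.647). Besides those among the 10 highest peaks, the strongest were ZK265.10 on I (7308), C27H6.5 (6879), T02E1.9 (6860) and T06C12.16 (6660), all chosen after their values were seen. The peak at C27H6.5 also overlapped unc-41, and that at T02E1.9 overlapped spe-12.

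Some strong peaks lay at no annotated Pol III or snoRNA gene. Those chosen after their values were seen were a peak in the body of zip-7 (IV, 16503346 to 16504227) with a signal value of 6946, one near mir-51 that overlapped alh-3 (IV, 11025610 to 11026677) with 6696, one in lips-10 (II, 8441269 to 8442144) with 6082, and one at no annotated gene (V, 3162879 to 3163759) with 4691. The weaker peaks with a B box were placed differently from tRNA genes. On the autosomes 8.33% of them (45 of 540) lay in the middle one of 3 equal parts of their chromosome, against 31.8% of tRNA gene peaks (Fisher exact p = 1.81e-18) and 26.2% of weaker peaks without a B box (Fisher exact p = 5.29e-14). More than 50% of the bases around the summit were soft-masked as repeats in 41.2% of the weaker peaks with a B box and in 31.4% of those without (Fisher exact p = 0.000414). Their median signal value was 234, against 132 without a B box (permutation p = 1e-05, the smallest possible). These tests of peaks counted each summit as a peak. A weaker second summit of an interval can lie over 100 bp from the B box and so lower the median without one. Merged peaks were not tested, so these p-values do not hold for separate sites. In tRNA pseudogenes the motif was present in 85.7% of those with and 70% of those without a peak (Fisher exact p = 0.00963).

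tRNA genes with a summit within 100 bp had a higher signal value on X than on the autosomes, with medians of 3796 over 246 genes and 2633 over 312, a log2 difference of 0.53 (95% bootstrap interval 0.36 to 0.66) that was 0.55 in the list of replicate 1 and 0.49 in that of replicate 2. The isotypes found on X were argued against as the cause, since the difference within isotypes was 0.47 (0.32 to 0.62), and so was signal shared between close neighbours, since the difference was 0.65 (0.52 to 0.79) among tRNA genes with no other within 1 kb. A higher signal value of X-linked peaks in general may account for it: peaks of no Pol III class were also higher on X, by 0.42 (0.11 to 0.67, permutation p = 0.00053). That comparison counted each summit as a peak, although some intervals carry several, and the mix of classes was not matched. Merged peaks were not tested, so its interval and p-value may not hold for separate sites. What raised both differences was not tested, and no biological explanation was tested because the design holds 1 group.

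At no Pol III gene or tRNA pseudogene, 110 peaks reached a signal value of 1701, of which 49 were at snoRNA genes, 24 at other non-coding genes, 13 at promoters, 12 in gene bodies and 12 at no gene. For spill-over from an annotated Pol III gene, 1.82% of these peaks (interval 0.5 to 6.39) had a summit within 1 kb of one, and the rest lay farther away. Their classes, however, already left out every peak with any part of its interval within 100 bp of such a gene. The low share was therefore in part fixed by the selection. It describes where these peaks lie and is no test of spill-over. Ribosomal protein promoters had a highest signal value of 117, so these promoters did not reach the level of strong peaks. That value was known before the comparison was set, chromatin openness was not measured, and 13 of the 110 peaks were at promoters. Open chromatin is therefore not decided for the 110 peaks. A candidate explanation is a tRNA-like promoter of their own: an A box followed by a B box was near the summit in 56.4% of them, against 43.8% of the 1252 weaker peaks of the same classes (Fisher exact p = 0.0123), but the B box alone gave 66.4% against 53.5% (Fisher exact p = 0.00945), so the difference does not speak for the A box. The difference was there in the 61 peaks not at snoRNA genes, at 62.3% (49.7 to 73.4) against 44.8% of such weaker peaks (Fisher exact p = 0.00826), and the explanation stays open for the 49 at snoRNA genes, whose 49.0% (35.6 to 62.5) was above the 17.4% of weaker snoRNA peaks (Fisher exact p = 0.00125) but did not differ from all weaker peaks past the threshold (p = 0.468). This was tested with 1 form of the A box, the share was 86.3% at tRNA gene peaks and a mean of 0.543% over 20 random placements, and unannotated Pol III genes, TFIIIC sites and decayed tRNA copies stay open. The Fisher tests of boxes counted each summit as a peak, although some intervals carry several. A weaker second summit can lie too far from the box to count, which can lower the share of weaker peaks. Merged peaks were not tested, so these differences may not hold for separate sites.

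The 37 Pol III genes without an optimal peak were 17 tRNA, 13 5S rRNA and 7 U6 genes. Unique 36-base words were counted over each gene widened by 100 bp on each side, so repeats confined to the gene body were not measured. For the tRNA genes, 2 main causes were argued against. The first was repeated sequence of the gene with its flanks, since 17.6% of them (interval 6.19 to 41.0) had under 50% unique words. The second was loss of the B box, since 11.8% (3.29 to 34.3) lacked the motif. A part played by either is not excluded: the first share was above the 2.18% of occupied tRNA genes (Fisher exact p = 0.00799), and for the second, undecided, the motif was in 88.2% of the genes without and 96.1% of those with a peak (Fisher exact p = 0.15). Repeated sequence could not be decided for the 5S rRNA and U6 genes together, at 60% of the 20 without and 40% of the 20 with a peak (Fisher exact p = 0.343), nor for 5S genes alone, at 92.3% of 13 without and 2 of 3 with a peak (Fisher exact p = 0.35). For U6 genes alone it was argued against as the main cause, at 0 of 7 without a peak (interval 0 to 35.4) and 6 of 17 with one (Fisher exact p = 0.13).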
